A study of Mus musculus with 15 samples.

How the data were processed

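Liver RNA of 15 mice, 5 in each of 3 groups, was measured with 1 array per mouse. Per the labels' protocols, 250 ng of total RNA was converted to sense-strand cDNA with the Ambion WT Expression kit and labelled with biotin with an Affymetrix WT Terminal Labeling kit. The deposited values had been computed with RMA, per the submitters' processing notes, which corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set. RMA's version was not given in the sources used here. The deposited table does not state its scale. Its highest value was 12.73, above 11.1, the natural log of the largest reading of a 16-bit scanner. The deposited values were therefore taken as log2 levels made by RMA, per the submitters' processing notes. No detection calls or scanner values were used here, so no level is given against background, and no dates of slides or scans were in the sources used here. RMA draws small differences of dim probe sets towards 0, and quantile normalization gives all arrays like distributions, so a change common to most genes would not be seen.

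The groups were taken from the sample titles. The labels name separate mice, so the p-values refer to the spread between mice. The sex of the mice was not given, and whether the CPT group stayed on the high-fat diet during its 8 weeks of treatment was not clear. No 2 arrays held the same values, and the smallest mean absolute difference between 2 arrays was 0.168 (log2). The deposited table held 409 repeated rows of values.

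Of 33649 probe sets, 25335 were listed with genes in the platform annotation, 23521 with 1 symbol and 1814 with several, and 8314 were not listed. Entrez identifiers of 23328 probe sets matched a table of RefSeq genes, and 0 symbols changed. Probe sets with exactly 1 symbol gave 22180 genes, each represented by its probe set with the highest mean over the 15 arrays, which mattered for the 1082 genes with over 1 probe set. Some called genes had a further probe set that did not follow the brightest, of which 4 examples were chosen after their values were seen. In HFD against NC that of Ptcd3 differed by 0.11 and that of Fau by 0.21, where the brightest differed by -0.43 and -0.35. The further probe sets had mean levels of 6.00 and 3.99. That of Cd9 differed by 0.01 and that of Pim1 by -0.17, both dim (1.97 and 1.74). No filter on low values was applied.

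Differences were tested with limma 3.58.1 in R 4.3.3 by linear models with a mean per group over all 15 arrays, 12 residual and 3.46 prior degrees of freedom, empirical Bayes moderation and 3 two-sided contrasts. The p-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, with a threshold of 0.05. SD is that of 5 mice and SE that of the fitted difference. Named genes were, for HFD against NC and for CPT against HFD, the 10 higher and 10 lower with the largest change among those past the threshold whose group ranges did not overlap and whose mean lay above that of the lowest 33.3% of genes (1.86, log2), and 5 each way for CPT against NC. Unnamed gene models, microRNA, olfactory and antibody segment genes were left out of this choice. Where fewer passed, the 5 with the smallest p each way were given as values. The members of each list with the smallest p, up to 4, the genes that changed in opposite directions in both contrasts, and the measured genes of a fixed set for lipids, glucose, inflammation and fibrosis were named whatever their values.

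Groups of genes were 23 pathway lists and 16 lists of cell type markers, 39 in all, with 605 of 675 listed genes measured. camera used a preset correlation of 0.01 between genes, and its p-values were adjusted over the 39 lists within a contrast. The calls were repeated with an estimated correlation and with fry, with statmod 1.5.0 at hand, which tests whether the genes of a list move one way on balance and does not compare them with other genes. The means of the lists per mouse are relative to the NC group mean. The lists, the tests, the rule for named genes and all alternatives but those said to be added later were chosen before the data were examined.

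The alternatives were leaving out the lowest 33.3% of genes, averaging a gene's probe sets, testing every probe set, a further quantile normalization, centring each array on its median, fitting only the 2 groups compared, mouse number as a block, a variance trend with robust moderation, array weights, a minimum change of 1.5-fold, a plain test per gene without moderation, and leaving out each array in turn. Leaving out CPT mice 1 and 4 together, and exact permutation of list means, were added after seeing the data, and fry was counted as an alternative then. For comparisons that share arrays, 100 simulations of groups without effects were run, and the shared arrays were split in all 20 ways into 2 and 3. The scripts were tested on simulated data with 22180 genes and 200 changed genes in each of 5 runs. Gene means came from all 15 arrays and the spread from within the 3 groups. The changed genes were drawn from those above the lowest 33.3% by mean level, so the shares found do not cover dimmer genes. For HFD against NC limma found 70% of 250 genes changed 1.5-fold and 92.4% of 250 changed 2-fold. It found 98% of those changed 3-fold and 98.8% of those changed 4-fold, and 59 of 998 calls (5.91%) were false. A list shifted by 0.3 (log2) was found in 5 of 5 runs. Its genes were simulated without correlation, so this does not show how camera performs on correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.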

Results

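Gene expression in the liver was measured in 15 C57BL6J mice, an inbred laboratory strain, on biotin-labelled Affymetrix arrays, 1 array per mouse. The mice formed 3 randomised groups of 5. The NC group ate normal diet for 20 weeks. The HFD group ate a high-fat diet for 20 weeks that held 2% cholesterol, 10% lard, 10% yolk and 0.5% bile sodium, with 30% of calories from fat. The CPT group had 12 weeks of the same high-fat diet and afterwards received triterpenic acids of Cyclocarya paliurus, a Chinese tree whose leaves are brewed as tea, by mouth at 160 mg/kg daily for 8 weeks. Whether these mice stayed on the high-fat diet during the treatment is not clear from the labels. All mice were fasted for 12 h before the liver was taken. Each array held 33649 probe sets, its median lay between 2.01 and 2.10 on the log2 scale, and the number of arrays limits the precision of every value here.

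The arrays of CPT mice 1 and 4 stood apart from the others. The first principal component held 21% of the variance, and on it these arrays scored 29.4 and 37.6, against -14.9 to 12.2 for the other 13. Each matched the other best of all arrays (r = 0.985), and their mean correlations with their own group were 0.982 and 0.980, against 0.984 to 0.990 elsewhere. In CPT mice 1 and 4 the log2 levels of Cidec, which encodes a protein that enlarges lipid droplets, were 6.50 and 7.57, against 2.24 to 4.03 in the other 13. Counts of genes are given without both as well, as are the means of the lists past the threshold that they move by over 1.5 times.

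**Figure D1:**
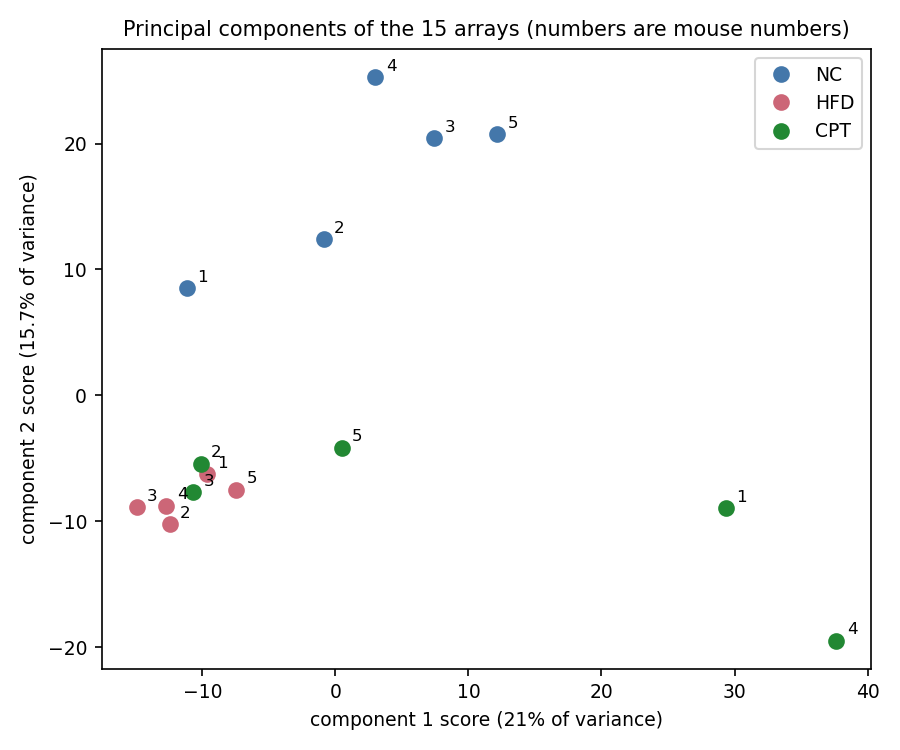
Scores of the 15 liver arrays on the first principal component (horizontal, 21% of the variance) and the second (vertical, 15.7%), both in units of log2 level, with a point per mouse numbered as in the text and coloured by group. CPT mice 1 and 4 lie at 29.4 and 37.6 on the first component, and the other 13 arrays lie between -14.9 and 12.2.

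The first comparison, HFD against NC, asked what the high-fat diet changed in the liver. Fasn, which encodes fatty acid synthase, fell from a log2 level of 7.63 ± 0.39 in NC to 5.49 ± 0.24 in HFD (SD, n = 5 mice each), and Acly, which supplies its acetyl-CoA, fell from 7.61 ± 0.36 to 5.81 ± 0.37. Tkfc, a kinase of fructose breakdown, fell from 9.12 ± 0.15 to 7.52 ± 0.44. Abcg5, which with Abcg8 exports sterols into bile, rose from 7.11 ± 0.33 to 8.56 ± 0.19. Hsd17b11, a dehydrogenase of lipid droplets, rose from 7.52 ± 0.26 to 8.76 ± 0.25, and Abcg2, an exporter of foreign compounds, from 6.52 ± 0.11 to 7.55 ± 0.13.

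By limma, 87 of 22180 genes passed an adjusted p of 0.05 in HFD against NC, 25 higher and 62 lower. Of these 87, 64 changed at least 1.5-fold, 20 higher and 44 lower. The ranges of the groups did not overlap for 635 genes, 2.86% of all, where chance gives 0.794%, and 83 of the 87 genes were among them. The 10 genes that rose most with separate ranges began with Rps12-ps24 (log2 fold change 1.94 ± 0.29 SE, adjusted p = 0.00683), Inmt, a methyltransferase (1.79 ± 0.32, adjusted p = 0.0239), Abcg5 (1.46 ± 0.19, adjusted p = 0.00293), and Ces1d, a carboxylesterase (1.30 ± 0.24, adjusted p = 0.0269). They were followed by Afmid, an enzyme of tryptophan breakdown (1.25, adjusted p = 0.0257), Hsd17b11 (1.25, adjusted p = 0.00233) and Mme, the peptidase neprilysin (1.24, adjusted p = 0.0225). The last of them were Abcg2 (1.04, adjusted p = 0.00187), Gpat4, an acyltransferase of glycerolipid synthesis (0.85, adjusted p = 0.0391) and Ces2a (0.76, adjusted p = 0.0130). Rps12-ps24 is a pseudogene of a ribosomal protein gene, so its signal is uncertain against that of its parent.

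The 10 that fell most began with Serpina7, the thyroxine-binding globulin (log2 fold change -3.46 ± 0.60 SE, adjusted p = 0.0204), Cxcl13, a chemokine that attracts B cells (-3.03 ± 0.56, adjusted p = 0.0286), and Rgs16, a regulator of G-protein signalling (-2.86 ± 0.58, adjusted p = 0.0465). Next came Fasn (-2.14 ± 0.26, adjusted p = 0.00187), Dusp1, a MAP kinase phosphatase (-2.03 ± 0.24, adjusted p = 0.00187), and Jchain, the joining chain of antibodies (-2.00 ± 0.36, adjusted p = 0.0239). The others were the transcription factor Klf10 (-1.83, adjusted p = 0.00654), Acly (-1.80, adjusted p = 0.00187), Tkfc (-1.60, adjusted p = 0.00187) and the clock repressor Bhlhe40 (-1.60, adjusted p = 0.00280). Khk, the fructose kinase that acts before Tkfc and was chosen after its values were seen, fell as well (-0.79, adjusted p = 0.00346).

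The split between higher and lower calls in HFD against NC moved with the scaling, from 25 and 62 to 41 and 40 of 81 genes after a further quantile normalization, with 62 genes shared. The count was 207 without CPT mice 1 and 4, which enter through the shared estimate of the spread, and 148 without NC 1. It was 39 without NC 4 or NC 5, 49 without HFD 1, 42 without HFD 2, 40 without HFD 4 and 33 without HFD 5. Of the 20 genes above, 11 passed in all 15 fits that left out 1 array: Rps12-ps24, Abcg5, Hsd17b11, Abcg2, Ces2a, Fasn, Dusp1, Klf10, Acly, Tkfc and Bhlhe40. Inmt missed the threshold without NC 5 or HFD 1, 2, 3 or 5 (adjusted p up to 0.0701) and Ces1d without NC 3, 4 or 5 or HFD 3, 4 or 5 (up to 0.0803). Afmid missed it without NC 4 or HFD 2, 3, 4 or 5 (up to 0.0728) and Mme without NC 4 or 5 or HFD 1, 4 or 5 (up to 0.0667). Serpina7 missed it without NC 4 or 5 or HFD 1, 2 or 5 (up to 0.0603) and Jchain without NC 5 or HFD 1, 2, 4 or 5 (up to 0.0701). Cxcl13 missed it without NC 4 or 5 or any HFD mouse (up to 0.0838). Gpat4 missed it in 10 of the 15 fits, all but those without NC 1 or CPT 1, 2, 3 or 4 (up to 0.0949). Rgs16 missed it in 12, all but those without HFD 5 or CPT 4 or 5 (up to 0.114).

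**Figure D2:**
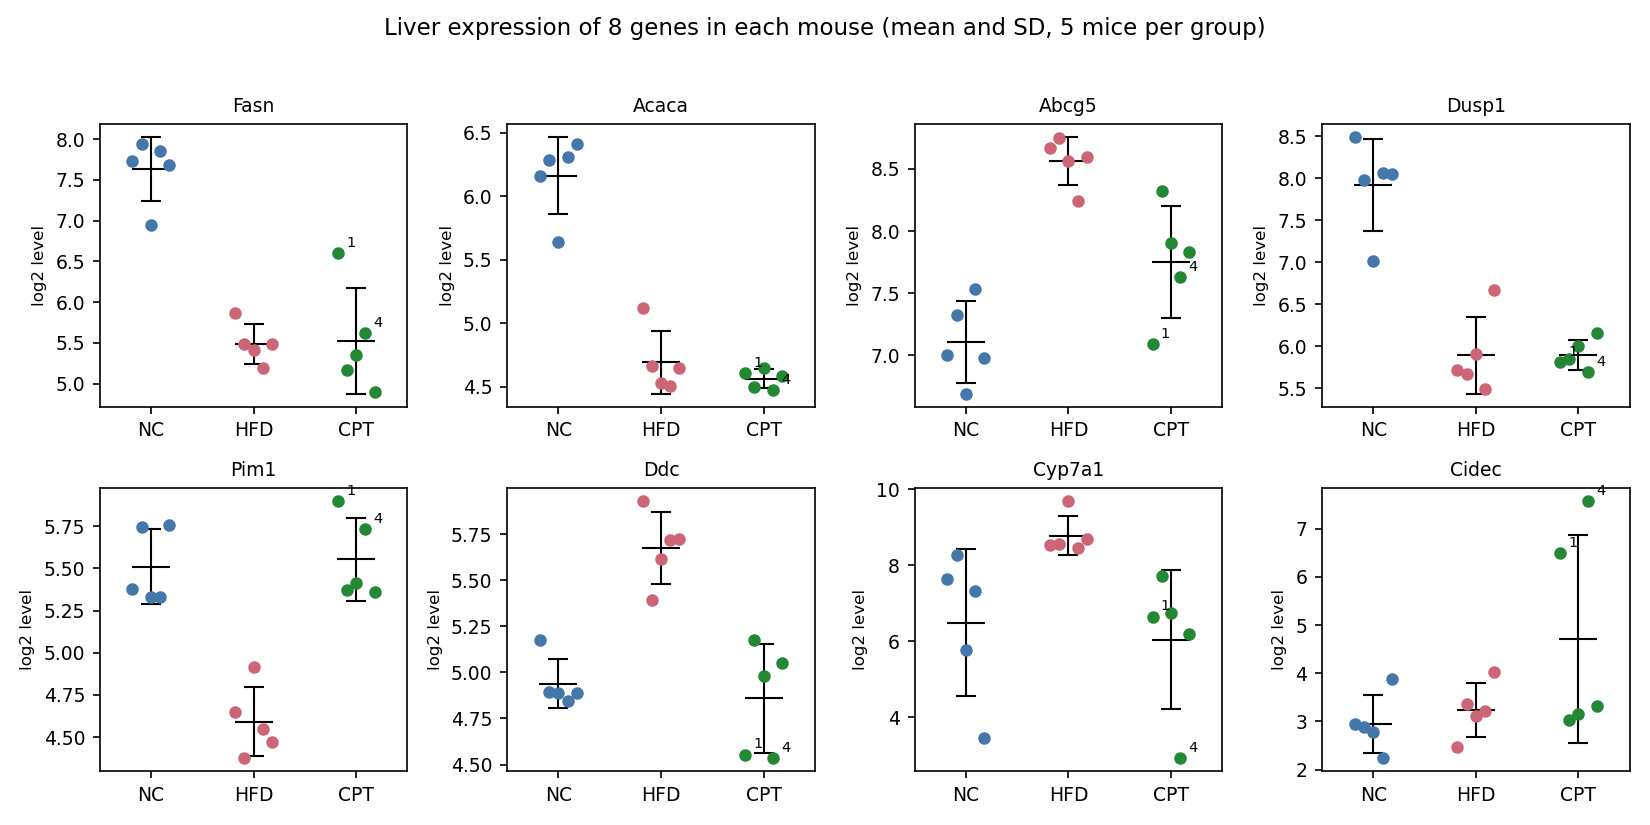
Log2 levels (vertical axes) of Fasn, Acaca, Abcg5, Dusp1, Pim1, Ddc, Cyp7a1 and Cidec in the livers of NC, HFD and CPT mice, with a point per mouse and the group mean with its SD as bars. Fasn and Acaca lie lower in HFD and CPT than in NC, Pim1 lies lower and Ddc higher in HFD than in NC and CPT, and CPT mice 1 and 4, which are numbered, hold Cidec levels of 6.50 and 7.57.

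Genes were then examined in fixed lists of pathways and cell type markers with camera. This tests whether a list shifts against all other genes. All 18 measured genes of cholesterol synthesis were lower in HFD than in NC, by a mean of -1.07 on the log2 scale (camera adjusted p = 2.43e-13, adjusted p = 0.188 with an estimated correlation). Tm7sf2, a sterol reductase (-1.39 ± 0.18 SE, adjusted p = 0.00233), and Dhcr7, which makes the last step to cholesterol (-1.04 ± 0.19, adjusted p = 0.0242), fell over all genes tested, and 16 members did not pass. Adjusted over the list alone, 10 fell, among them Nsdhl at -2.45 (adjusted p over all genes 0.0516). Sqle, the squalene epoxidase, at -1.91, was another (0.369). The list mean of each HFD mouse lay between -1.15 and -0.99 against the NC mean, and those of the NC mice between -0.33 and 0.30.

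The list of fatty acid synthesis shifted lower in HFD, by a mean of -0.69 over 19 genes (camera adjusted p = 3.16e-11, adjusted p = 0.0863 with an estimated correlation). Over all genes tested, 6 members fell, 1 rose and 12 did not pass, and adjusted over the list alone 10 fell and 1 rose. Acaca, the acetyl-CoA carboxylase that makes malonyl-CoA, fell from 6.16 ± 0.31 to 4.69 ± 0.25 (SD, n = 5 each), a log2 fold change of -1.47 with an adjusted p of 0.000284. Pklr, the pyruvate kinase of liver, fell by 1.41 (adjusted p = 0.00936), and Fads2, a desaturase of polyunsaturated fatty acids, rose by 0.59 (adjusted p = 0.0483). Scd1, which makes oleate, differed by -0.36 (adjusted p = 0.541) and its regulator Srebf1 by 0.47 (adjusted p = 0.549).

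The list of sterol efflux and LXR targets shifted higher in HFD, by a mean of 0.34 over 11 genes (camera adjusted p = 0.00190, adjusted p = 0.115 with an estimated correlation). Abcg5 alone rose over all genes tested and 10 members did not pass. In the list 4 rose adjusted over the list alone, with Abcg8 at 1.16 (adjusted p over all genes 0.0812) and Apoe at 0.31 (0.0618). Bile acid synthesis shifted higher by 0.41 over 12 genes (camera adjusted p = 0.00780, adjusted p = 0.177 with an estimated correlation). By limma 0 members passed either way of adjusting and 5 had an unadjusted p under 0.05. Cyp7a1, its rate-limiting enzyme, was at 8.79 ± 0.51 in HFD and 6.50 ± 1.93 in NC (SD, n = 5 each; limma adjusted p = 0.330). The list of fatty acid oxidation and PPARA targets shifted higher by 0.37 over 27 genes (camera adjusted p = 3.87e-05, adjusted p = 0.441 with an estimated correlation). Of these, Acaa1b, a thiolase of peroxisomes, rose over all genes tested (1.27, adjusted p = 0.0484), 26 did not pass, and adjusted over the list alone 5 rose and 1 fell. Cpt1a, which brings fatty acids into mitochondria, differed by 0.14 (adjusted p = 0.674). NC mouse 4 stood at -0.71 on this list and NC mouse 1 at 0.61, where the HFD mice lay between 0.05 and 0.75. Without NC 4 the shift was 0.19 (camera adjusted p = 0.00841).

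The list of glucose metabolism and insulin signalling shifted lower in HFD, by -0.32 over 17 genes (camera adjusted p = 0.00266, adjusted p = 0.177 with an estimated correlation, and 0.0664 after a further quantile normalization). Irs2, an adaptor of the insulin receptor, fell by 1.26 (adjusted p = 0.0165), or 0.0555 without HFD 5. The other 16 members did not pass over all genes. Within the list, 3 fell adjusted over the list alone, with Igfbp1, a binding protein of insulin-like growth factors, at -2.18 (adjusted p over all genes 0.185). Pck1, of glucose synthesis, differed by 0.06 (adjusted p = 0.937) and Irs1 by 0.38 (adjusted p = 0.569). Immediate early genes, which respond within minutes to stimuli, shifted lower by -0.42 over 16 genes (camera adjusted p = 1.03e-07, adjusted p = 0.0863 with an estimated correlation). Dusp1 fell over all genes, 15 did not pass, and 8 fell adjusted over the list alone. The list of the unfolded protein response shifted lower by -0.21 over 20 genes (camera adjusted p = 0.000542, adjusted p = 0.430 with an estimated correlation). By limma 0 of its members passed over all genes and 6 had an unadjusted p under 0.05. Adjusted over the list alone 3 fell and 1 rose, with Xbp1, a transcription factor of this response, at -0.83 (adjusted p over all genes 0.137) and Asns, the asparagine synthetase, at 2.07 (0.0601). Male-biased liver genes shifted higher by 0.32 over 18 genes (camera adjusted p = 0.00482, adjusted p = 0.406 with an estimated correlation). Without NC 4 their shift was 0.20 (adjusted p = 0.0526). Over all genes 1 of them, Susd4, fell (-1.39, adjusted p = 0.0423) and 17 did not pass. In this list 2 rose and 1 fell adjusted over the list alone, with Cyp4a12a, a fatty acid hydroxylase, at 0.79 (adjusted p over all genes 0.0595).

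Acute phase genes, which encode plasma proteins made in inflammation, shifted lower in HFD than in NC by a mean of -0.999 over 21 genes (camera adjusted p = 3.70e-11, adjusted p = 0.188 with an estimated correlation). Over all genes 0 passed by limma and 12 had an unadjusted p under 0.05. In this list 8 fell adjusted over the list alone, with Orm3, an orosomucoid, at -3.83 and Lcn2, a siderophore-binding protein, at -1.73 (adjusted p over all genes 0.0595 and 0.302). NC mouse 1 lay apart on this list, at -1.22 against -0.12 to 0.59 in the other NC mice, and at a Saa2 level of 4.46 against 9.71 to 11.9 in the others. Kupffer cell markers shifted lower by -0.45 over 12 genes (camera adjusted p = 3.87e-07, adjusted p = 0.199 with an estimated correlation). Of them 0 passed by limma over all genes, 7 were at an unadjusted p under 0.05, and 5 fell adjusted over the list alone. Among these were Marco, a scavenger receptor, at -1.06 (adjusted p over all genes 0.131) and C1qb, of complement, at -0.63 (0.166). Neutrophil markers shifted lower by -0.46 over 12 genes (camera adjusted p = 0.00111, adjusted p = 0.199 with an estimated correlation). By limma 0 passed over all genes and 6 had an unadjusted p under 0.05. Adjusted over the list alone 4 fell and 1 rose, with S100a8 at -1.72 and S100a9 at -1.10 (adjusted p over all genes 0.306 and 0.256). NC mouse 4 held the highest list mean for neutrophils, 0.76, and for Kupffer cells, 0.44. Without NC 4 the neutrophil shift was -0.27 (camera adjusted p = 0.00913), and NC mice 1 and 2 stood at -0.46 and -0.43, among the HFD mice (-0.52 to -0.40).

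The list of monocyte-derived and lipid-associated macrophages shifted lower by -0.24 over 13 genes in HFD against NC (camera adjusted p = 0.0280, adjusted p = 0.406 with an estimated correlation). Cd9, a tetraspanin, fell by 0.79 (adjusted p = 0.0164) and 12 members did not pass. With Itgam (-0.87, adjusted p over all genes 0.0538) 2 fell adjusted over the list alone. This call was lost without NC 3 (adjusted p = 0.0546), NC 4 (0.0846, with a shift of -0.15), HFD 4 (0.0776) or HFD 5 (0.0563). Markers of stellate cells shifted lower by -0.19 over 14 genes (camera adjusted p = 0.00937, adjusted p = 0.295 with an estimated correlation). Those of sinusoidal endothelial cells shifted lower by -0.18 over 14 genes (camera adjusted p = 0.0267, adjusted p = 0.441 with an estimated correlation). In each, by limma 0 members passed over all genes and 4 had an unadjusted p under 0.05, with 0 and 1, Oit3, that fell adjusted over the list alone. The stellate cell call was lost without HFD 2 (0.0736), and the endothelial one without NC 4 (0.0768), NC 5 (0.134), HFD 1 (0.113), HFD 2 (0.0736) or HFD 4 (0.0776). After a further quantile normalization the adjusted p of these 2 lists was 0.0873 and 0.223. Without the lowest 33.3% of genes the macrophage, stellate and endothelial lists missed the threshold (0.0894, 0.0604 and 0.119). The macrophage and endothelial lists also missed it with each array centred on its median (0.0550 and 0.0572) and with only the 2 groups in the fit (0.0549 for both). Genes of oxidative phosphorylation shifted higher by 0.06 over 27 genes (camera adjusted p = 0.0469, adjusted p = 0.452 with an estimated correlation). By limma 0 members passed either way of adjusting and 5 were at an unadjusted p under 0.05. That call was lost without NC 2, 3, 4 or 5 (adjusted p 0.0530, 0.237, 0.0846 and 0.0681, with a shift of 0.04 without NC 3), HFD 2, 3, 4 or 5 (0.0670, 0.109, 0.0725 and 0.108), or CPT mice 1 and 4 together (0.0508). It was also lost with the mean of a gene's probe sets (0.0563), with each array centred on its median (0.0582) and with a variance trend (0.116).

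In all, 16 of 39 lists passed in HFD against NC, 5 higher and 11 lower, 0 with an estimated correlation and 3 by fry, those of fatty acid synthesis, sterol efflux and immediate early genes. Among the 23 lists that did not pass were lipid droplets and fatty acid uptake (mean 0.08, adjusted p = 0.520), cytokines (-0.24, adjusted p = 0.177, or 0.0193 without NC 1), extracellular matrix and fibrosis (-0.02, adjusted p = 0.724) and hepatocyte markers (0.02, adjusted p = 0.661). Of immune cells, markers of T cells (0.03, adjusted p = 0.520), natural killer cells (0.01, adjusted p = 0.845), dendritic cells (-0.13, adjusted p = 0.239) and B and plasma cells (-0.30, adjusted p = 0.0991, or 0.0355 without NC 1) did not pass. Xenobiotic cytochromes P450 and CAR/PXR targets (0.07, adjusted p = 0.114) passed, higher, after a further quantile normalization (0.0276), with each array centred on its median (0.0306), without the lowest 33.3% of genes (0.0206) or without NC 1 (0.0293). Plin2, a lipid droplet coat protein, differed by -0.34 (adjusted p = 0.663) and Cd36, a fatty acid transporter, by 0.30 (adjusted p = 0.836). Cidec differed by 0.29 (adjusted p = 0.929), the cytokine Tnf by 0.07 (adjusted p = 0.866) and Col1a1, of fibrillar collagen, by 0.01 (adjusted p = 0.981). The mean of the hepatocyte list was above 0 and its median below. The NRF2 and glutathione list had a mean of -0.04, a median of 0.06 and a test that pointed higher (adjusted p = 0.787).

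**Figure D3:**
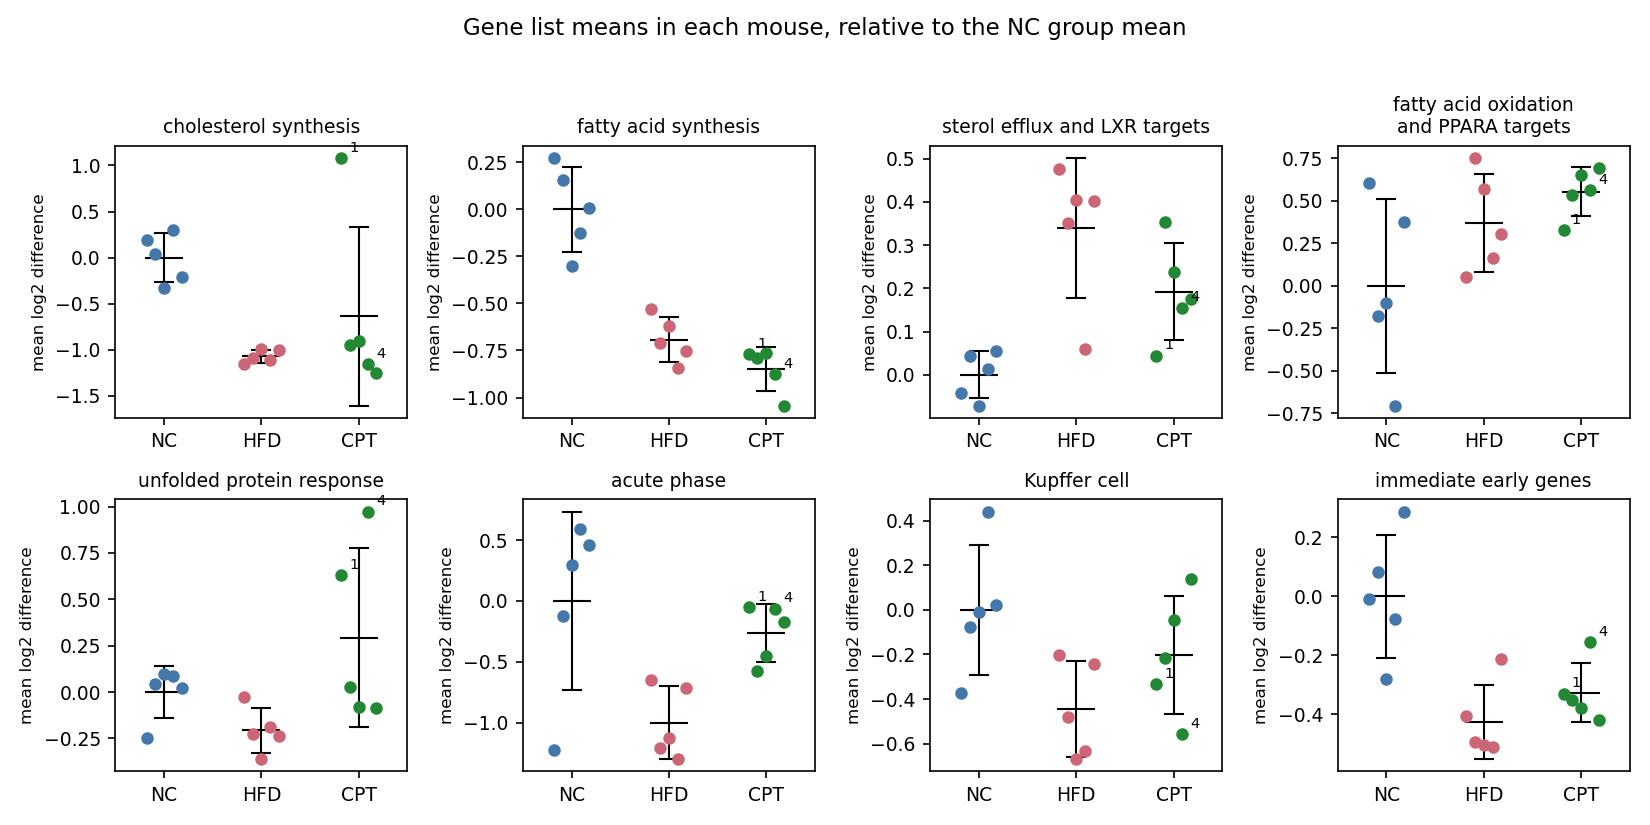
Mean log2 difference of each gene list from the NC group mean (vertical axes) for 8 lists in NC, HFD and CPT mice, with a point per mouse and the group mean with its SD as bars. Cholesterol synthesis lies between -1.15 and -0.99 in HFD mice and at 1.08 in CPT mouse 1, and the unfolded protein response lies at 0.63 and 0.97 in CPT mice 1 and 4.

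The second comparison, CPT against HFD, asked how livers of mice given the triterpenic acids after 12 weeks of high-fat diet differed from those of mice that ate it for 20 weeks. As the diet of the CPT mice during the treatment is not clear, the contrast cannot part the acids from a change of diet. Pim1, a serine/threonine kinase induced by cytokines, rose from 4.59 ± 0.21 in HFD to 5.55 ± 0.25 in CPT (SD, n = 5 each), and Pik3ap1, an adaptor of PI3-kinase, rose from 6.88 ± 0.15 to 7.79 ± 0.32. Plin3, a coat protein of lipid droplets, rose from 4.57 ± 0.08 to 5.10 ± 0.10. Josd2, a deubiquitinase, rose from 3.31 ± 0.13 to 3.91 ± 0.11, and Gdf2, which encodes the signalling protein BMP9, from 3.52 ± 0.09 to 4.02 ± 0.13. Ddc, the decarboxylase that makes dopamine and serotonin, fell from 5.68 ± 0.19 to 4.86 ± 0.30.

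These 6 genes, 5 higher and 1 lower, were all that passed by limma, and their group ranges did not overlap. Their log2 fold changes were 0.96 ± 0.13 SE for Pim1, 0.91 ± 0.13 for Pik3ap1 and 0.60 ± 0.08 for Josd2 (adjusted p = 0.0211 for each of the 3). The others were 0.53 ± 0.08 for Plin3 (adjusted p = 0.0257), 0.50 ± 0.07 for Gdf2 (adjusted p = 0.0252) and -0.82 ± 0.13 for Ddc (adjusted p = 0.0415). Of the 6, 4 changed at least 1.5-fold, 3 higher and 1 lower. Among all 22180 genes 2329 had an unadjusted p under 0.05, 1412 higher and 917 lower, where chance gives 1109. Ranges did not overlap for 358 genes, 1.61% of all against 0.794% by chance. The lower genes with the next smallest p did not pass: Eny2 at -0.46 (adjusted p = 0.0724), Clpx, a mitochondrial chaperone, at -0.87 (adjusted p = 0.131), Cyp2u1 at -1.34 (adjusted p = 0.135) and Baiap2 at -0.64 (adjusted p = 0.135). Fasn, which fell under the diet, was at 5.52 ± 0.65 in CPT against 5.49 ± 0.24 in HFD (SD, n = 5 each; log2 fold change 0.04, adjusted p = 0.979). Cyp7a1 was at 6.05 ± 1.83 in CPT (-2.74, adjusted p = 0.290), Abcg5 at 7.75 ± 0.45 (-0.81, adjusted p = 0.179) and Scd1 at 9.81 ± 0.32 (-0.81, adjusted p = 0.179).

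Each of the 6 calls in CPT against HFD was lost when some single arrays were left out: 0 genes passed by limma without HFD 1, 2, 4 or 5. By contrast 13 passed without CPT 2 and 19 without CPT 3. Without HFD 4 the adjusted p of Pim1, Pik3ap1, Josd2 and Gdf2 was 0.0804, without HFD 5 that of Plin3 was 0.0979, and without HFD 1 that of Ddc was 0.135, the highest of each over the 15 fits. Beyond HFD 1, 2, 4 and 5, Pik3ap1 missed the threshold without CPT 1, Plin3 without NC 3, NC 5 or CPT 1, Gdf2 without HFD 3 or CPT 4, and Ddc without NC 2, 3, 4 or 5, HFD 3 or CPT 1 or 4. In the fits that lost the call the fold changes lay between 0.91 and 0.98 for Pim1, 0.85 and 0.95 for Pik3ap1, and 0.55 and 0.63 for Josd2. They lay between 0.51 and 0.54 for Plin3, 0.47 and 0.54 for Gdf2, and -0.89 and -0.74 for Ddc. Without CPT mice 1 and 4 together 4 genes passed, 3 higher and 1 lower, and 0 of them were among the 6. The split was 3 higher and 2 lower after a further quantile normalization, with 4 genes shared, and 5 higher and 0 lower with each array centred on its median, with 5 shared.

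In the gene lists, 9 of 39 passed in CPT against HFD, 7 higher and 2 lower, while 0 passed with an estimated correlation (adjusted p = 0.635 for each of the 9) and 0 by fry. The higher and lower lists were 3 and 3 after a further quantile normalization and 6 and 3 with each array centred on its median. The unfolded protein response shifted higher by a mean of 0.50 over 20 genes (camera adjusted p = 6.01e-08, adjusted p = 0.635 with an estimated correlation). By limma 0 members passed over all genes and 11 had an unadjusted p under 0.05. Adjusted over the list alone 10 rose, among them Xbp1 at 1.20, the chaperone Hyou1 at 1.37 and the transcription factor Atf4 at 0.57 (adjusted p over all genes 0.105, 0.179 and 0.179). The list moved with the arrays that stood apart: CPT mice 4 and 1 had list means of 0.97 and 0.63 against the NC mean, and CPT mice 2, 3 and 5 of 0.03, -0.08 and -0.09. The HFD mice lay between -0.36 and -0.03. Without CPT 4 the shift was 0.33 (camera adjusted p = 2.05e-05), and without CPT mice 1 and 4 it was 0.16 (0.00216).

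Acute phase genes shifted higher in CPT than in HFD by 0.74 over 21 genes (camera adjusted p = 2.92e-07, adjusted p = 0.635 with an estimated correlation). By limma 0 passed either way of adjusting and 6 had an unadjusted p under 0.05, with Saa2 at 3.25, Orm3 at 2.24 and Lcn2 at 1.63 (adjusted p 0.369, 0.348 and 0.367). The acute phase list means of the 5 CPT mice, from -0.57 to -0.05, lay above those of the 5 HFD mice, from -1.30 to -0.65. Genes of oxidative phosphorylation shifted lower by -0.11 over 27 genes, 26 of them lower (camera adjusted p = 6.36e-05, adjusted p = 0.635 with an estimated correlation). Of these, 0 passed by limma over all genes and 3 had an unadjusted p under 0.05. Ndufb3, a subunit of complex I, fell adjusted over the list alone (-0.40, adjusted p over all genes 0.179). Cholesterol synthesis shifted higher by 0.43 over 18 genes (camera adjusted p = 0.00773, adjusted p = 0.635 with an estimated correlation). By limma 0 passed either way of adjusting and 2 were at an unadjusted p under 0.05. That shift lay in CPT mouse 1, whose list mean was 1.08 against the NC mean, where the other CPT mice lay between -1.25 and -0.91. Without this array the shift was 0.01 (adjusted p = 0.894). Without CPT mice 1 and 4 it was 0.04 (adjusted p = 0.773).

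Kupffer cell markers shifted higher in CPT than in HFD by 0.24 over 12 genes (camera adjusted p = 0.00773, adjusted p = 0.635 with an estimated correlation), with C1qb at 0.51 (limma adjusted p = 0.318). The call was lost without CPT 3 (0.0543) or CPT 5 (0.131, with a shift of 0.16), and the shift was 0.41 without CPT mice 1 and 4. Pericentral hepatocyte markers (0.19 over 11 genes, camera adjusted p = 0.0333), sinusoidal endothelial markers (0.19 over 14, camera adjusted p = 0.0347) and stellate cell markers (0.13 over 14, camera adjusted p = 0.0415) shifted higher. Male-biased liver genes shifted lower (-0.29 over 18, camera adjusted p = 0.0440). Each of these had an adjusted p of 0.635 with an estimated correlation. By limma 0 members of these 5 lists passed over all genes, and 2, 1, 4, 3 and 2 had an unadjusted p under 0.05. Adjusted over the list alone 1 passed, the male-biased Cyp2u1, which fell. The pericentral call was lost without HFD 1, 4 or 5 (0.0982, 0.0829 and 0.0686) or CPT 3 or 5 (0.158 and 0.187). The endothelial call was lost without HFD 1, 2 or 4 (0.117, 0.0796 and 0.106) or CPT 2, 3 or 5 (0.0672, 0.186 and 0.0832). The stellate call was lost without HFD 1, 2 or 5 (0.0687, 0.159 and 0.0612), CPT 2, 4 or 5 (0.0599, 0.225 and 0.131), or CPT 1 and 4 together (0.110), and its shift was 0.08 without CPT 4. The male-biased call was lost without NC 1 (0.0535), HFD 1, 4 or 5 (0.0983, 0.106 and 0.0749) or CPT 1, 2, 3 or 5 (0.272, 0.0559, 0.0543 and 0.131), and its shift was -0.19 without CPT 1. After a further quantile normalization the Kupffer, pericentral, endothelial and stellate lists missed the threshold (adjusted p 0.0513, 0.136, 0.182 and 0.149). Without the lowest 33.3% of genes the pericentral, endothelial and stellate lists did (0.0785, 0.0812 and 0.105). The pericentral list also missed it with the mean of a gene's probe sets (0.0816), and the stellate list with each array centred on its median (0.0570).

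The other lists did not pass in CPT against HFD, among them fatty acid synthesis (-0.16, adjusted p = 0.238), fatty acid oxidation (0.19, adjusted p = 0.150), sterol efflux (-0.15, adjusted p = 0.350), lipid droplets (0.23, adjusted p = 0.151) and bile acid synthesis (-0.33, adjusted p = 0.0610, or 0.0158 after a further quantile normalization). Bile acid synthesis also passed with each array centred on its median (0.0421), with only the 2 groups in the fit (0.0223), and without NC 4, NC 5, HFD 2, CPT 2 or CPT 4 (adjusted p down to 0.0378), and fatty acid oxidation without HFD 2, HFD 3 or CPT 1 (down to 0.0174). Without CPT mice 1 and 4, 6 further lists passed, all higher. They were xenobiotic cytochromes P450 (adjusted p = 0.000564), bile acid transport and FXR targets (0.00183), lysosome and autophagy (0.00188), NRF2 and glutathione (0.00955), fatty acid oxidation (0.0124) and interferon response (0.0383). The lipid genes Srebf1 (-0.59, adjusted p = 0.442), Cpt1a (0.23, adjusted p = 0.472), Cd36 (0.28, adjusted p = 0.859) and Plin2 (0.33, adjusted p = 0.690) did not pass, nor did Abcg8 (-0.62, adjusted p = 0.441) and Sqle (1.12, adjusted p = 0.657). Cidec was at 4.71 ± 2.15 in CPT and 3.24 ± 0.55 in HFD (SD, n = 5 each; limma adjusted p = 0.508). Irs1 (-0.53, adjusted p = 0.412), Pck1 (-0.06, adjusted p = 0.938), Tnf (-0.07, adjusted p = 0.877) and Col1a1 (0.04, adjusted p = 0.948) did not pass either. The list of glucose metabolism had a mean of 0.01 and a test that pointed lower. Those of cytokines and lysosome had means of 0.14 and 0.08 with medians of -0.02 and -0.01.

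The third comparison, CPT against NC, asked what differed from normal diet in the treated mice. Acaca stood at 4.56 ± 0.08 in CPT against 6.16 ± 0.31 in NC (SD, n = 5 each) and Fasn at 5.52 ± 0.65 against 7.63 ± 0.39, and both fell. Asns rose from 4.01 ± 0.76 to 6.73 ± 0.76, and Hspa1b, an inducible heat shock protein, from 3.66 ± 0.16 to 5.62 ± 0.50. Tkfc fell from 9.12 ± 0.15 to 6.95 ± 0.34, and Khk fell by 1.17 (adjusted p = 9.32e-05).

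By limma 102 genes passed in CPT against NC, 25 higher and 77 lower, and 73 of them changed at least 1.5-fold. Group ranges did not overlap for 462 genes, 2.08% of all against 0.794% by chance, 95 of them among the 102. The 5 genes that rose most with separate ranges included Asns (log2 fold change 2.72 ± 0.45 SE, adjusted p = 0.0122), Hspa1b (1.97 ± 0.32, adjusted p = 0.0101), and Hsph1, a further heat shock protein (1.94 ± 0.37, adjusted p = 0.0273). With them were Rps12-ps24 (1.67, adjusted p = 0.0145) and Ehhadh, an enzyme of peroxisomal fatty acid oxidation (1.61, adjusted p = 0.0349). The 5 that fell most were Rgs16 (-2.76, adjusted p = 0.0489), Defa21, an alpha-defensin (-2.59, adjusted p = 0.0280), Jchain (-2.24, adjusted p = 0.00906), Tkfc (-2.17, adjusted p = 7.08e-05) and Fasn (-2.11, adjusted p = 0.00139). Of these 10, 6 passed in all 15 fits that left out an array. Hsph1 missed the threshold without NC 2, 3, 4 or 5 (adjusted p up to 0.0744) and Defa21 without NC 3, 4 or 5 or CPT 4 or 5 (up to 0.0708). Ehhadh missed it without NC 2, 3 or 4, HFD 3, 4 or 5 or CPT 3, 4 or 5 (up to 0.0887) and Rgs16 without any array but HFD 4, HFD 5 or CPT 4 (up to 0.109). The count was 68 without NC 4, its lowest with 1 array left out, and 134 without CPT mice 1 and 4, with 62 genes shared. Cyp7a1 (-0.45, adjusted p = 0.912), Abcg5 (0.65, adjusted p = 0.196) and Abcg8 (0.55, adjusted p = 0.505) did not pass. Cd36 (0.58, adjusted p = 0.641), Cidec (1.77, adjusted p = 0.411) and Srebf1 (-0.12, adjusted p = 0.922) did not either.

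Of 39 lists, 13 passed in CPT against NC, 5 higher and 8 lower, and 1 of them also passed with an estimated correlation and by fry, that of fatty acid synthesis. This list shifted lower by -0.85 over 19 genes (camera adjusted p = 4.54e-16, adjusted p = 0.0259 with an estimated correlation). Over all genes 6 members fell, among them Acaca (-1.60, adjusted p = 7.08e-05), Pklr (-2.03, adjusted p = 0.000503) and Scd1 (-1.17, adjusted p = 0.0128). Fads2 rose (0.96, adjusted p = 0.00160) and 12 did not pass. In this list 12 fell and 1 rose adjusted over the list alone. Fatty acid oxidation and PPARA targets shifted higher by 0.55 over 27 genes (camera adjusted p = 1.37e-08, adjusted p = 0.336 with an estimated correlation). Ehhadh rose over all genes, 26 did not pass, and 9 rose adjusted over the list alone, with Cpt1a at 0.37 (adjusted p over all genes 0.168). Cholesterol synthesis shifted lower by -0.64 over 18 genes (camera adjusted p = 1.38e-06, adjusted p = 0.417 with an estimated correlation). Tm7sf2 (-1.06, adjusted p = 0.0125) and Dhcr7 (-0.98, adjusted p = 0.0280) fell, 16 did not pass, and 6 fell adjusted over the list alone. In this list CPT mouse 1 stood at 1.08 above the NC mean. Without it the shift was -1.06 (camera adjusted p = 3.96e-28), and without CPT mice 1 and 4 it was -1.03. Glucose metabolism shifted lower by -0.31 over 17 genes (camera adjusted p = 0.00113, adjusted p = 0.177 with an estimated correlation). Pygl, the glycogen phosphorylase of liver, fell (-1.05, adjusted p = 0.00521), 16 did not pass, and adjusted over the list alone 6 fell and 1 rose. Immediate early genes shifted lower by -0.33 over 16 genes (camera adjusted p = 2.09e-05, adjusted p = 0.177 with an estimated correlation). Dusp1 fell either way of adjusting (-2.02, adjusted p = 0.00114) and 15 did not pass.

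Xenobiotic cytochromes P450 and CAR/PXR targets shifted higher in CPT than in NC by 0.26 over 28 genes (camera adjusted p = 0.000501, adjusted p = 0.336 with an estimated correlation). By limma 0 passed over all genes and 8 had an unadjusted p under 0.05. Cyp1a2 and Cyp2e1 were the 2 that rose adjusted over the list alone. Without CPT mice 1 and 4 the shift was 0.41 (camera adjusted p = 4.87e-07). Neutrophil markers shifted lower by -0.39 over 12 genes (camera adjusted p = 0.00468, adjusted p = 0.336 with an estimated correlation). By limma 0 passed either way of adjusting and 3 were at an unadjusted p under 0.05. NC mouse 4 held the highest list mean, 0.76, and without it the shift was -0.20 (camera adjusted p = 0.0493). Lipid droplet genes (0.31 over 18, camera adjusted p = 0.0125), sterol efflux genes (0.19 over 11, camera adjusted p = 0.0297) and NRF2 and glutathione genes (0.16 over 21, camera adjusted p = 0.0373) shifted higher. In that order they had an adjusted p of 0.336, 0.336 and 0.563 with an estimated correlation. By limma 0 of their members passed over all genes, 4, 4 and 6 had an unadjusted p under 0.05, and 0, 3 and 1 rose adjusted over the list alone. B and plasma cell markers (-0.35 over 10, camera adjusted p = 0.0291), lipid-associated macrophage markers (-0.21 over 13, camera adjusted p = 0.0291) and Kupffer cell markers (-0.20 over 12, camera adjusted p = 0.0373) shifted lower. In that order they had an adjusted p of 0.336, 0.384 and 0.646 with an estimated correlation. Over all genes Jchain fell in the first (adjusted p = 0.00906), Cd9 in the second (-0.76, adjusted p = 0.0139), and by limma 0 in the third, where 1 had an unadjusted p under 0.05. In these lists 3, 2 and 1 fell adjusted over the list alone.

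These last 6 calls in CPT against NC were lost when some single arrays were left out. Lipid droplets missed the threshold without NC 4 (0.0973), CPT 5 (0.0527) or CPT 1 and 4 together (0.0699), and CPT mice 1 and 4 held list means of 0.46 and 0.63. The lipid droplet shift was 0.19 without NC 4 and 0.15 without both CPT mice. Sterol efflux missed it without CPT 2 (0.0929) or CPT 3 (0.0554), and NRF2 and glutathione without NC 2, 3 or 5 (0.111, 0.0704 and 0.125) or CPT 2 or 3 (0.157 and 0.155). B and plasma cells missed it without NC 5 (0.0702), CPT 4 (0.104) or CPT 1 and 4 together (0.235). Lipid-associated macrophages missed it without NC 4 (0.0927), CPT 1, 2 or 4 (0.0552, 0.0616 and 0.0942) or CPT 1 and 4 together (0.235), and their shift was -0.12 without NC 4. Kupffer cells missed it without NC 4 or 5 (0.286 and 0.0702), CPT 1, 2 or 4 (0.168, 0.0706 and 0.251) or CPT 1 and 4 together (0.926). They also missed it after a further quantile normalization (0.0651), without the lowest 33.3% of genes (0.0907), with each array centred on its median (0.0605) and with array weights (0.119). B and plasma cells missed it without the lowest 33.3% of genes as well (0.0649). The Kupffer cell shift was -0.09 without NC 4, -0.11 without CPT 4 and -0.04 without CPT mice 1 and 4. With 1 array left out and the call lost, the shift lay between 0.15 and 0.18 for sterol efflux, 0.12 and 0.14 for NRF2 and glutathione, and -0.31 and -0.30 for B and plasma cells. It lay between 0.19 and 0.29 for lipid droplets and between -0.20 and -0.12 for lipid-associated macrophages. The acute phase list did not pass (adjusted p = 0.124) but did so without NC 1 (8.69e-07), CPT 4 (0.0403) or CPT mice 1 and 4 (0.0260). Bile acid transport and FXR targets (0.00453) and pericentral markers (0.0202), both higher, also passed without CPT mice 1 and 4. The unfolded protein response, higher by 0.29, did not pass (adjusted p = 0.0595) but did so after a further quantile normalization (0.0213), with each array centred on its median (0.0313) or without the lowest 33.3% of genes (0.0379). It also passed without NC 3 or 4 (0.0476 and 0.0493) or CPT 2, 3 or 5 (0.0212, 0.00494 and 0.00488), and its shift was -0.05 without CPT mice 1 and 4 (0.0574).

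The comparisons share arrays, so their overlaps were set beside simulated groups without effects. HFD and CPT livers shared 6 genes higher than NC: Afmid, Ces2a, Ces3a, Fads2, Hsd17b11 and Rps12-ps24. They shared 31 genes lower than NC, among them Acaca, Acly, Fasn, Khk, Pklr, Tkfc, Dusp1 and Jchain, examples chosen after the overlap was seen. Independent lists would share 0.0282 higher and 0.215 lower genes, and 100 simulations with shared NC arrays gave 0. As 0 of these simulations had calls in both contrasts, that 0 gives no chance level for the overlap. With the NC arrays split so that none entered both contrasts, a median of 8.5 genes were shared in the same direction over 20 splits, from 1 to 12, where independent lists would share at most 0.181. The covariance of the log2 fold changes over genes was 0.0245, against 0.00931 in the simulations, a difference of 0.0152. With the NC arrays split its median was 0.0174, from 0.00658 to 0.0226.

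Of the 87 genes changed by the diet, 3 changed the opposite way in CPT against HFD. Pim1 and Gdf2 fell in HFD (-0.92, adjusted p = 0.00554, and -0.40, adjusted p = 0.0262) and rose in CPT, and Ddc rose in HFD (0.74, adjusted p = 0.0215) and fell in CPT. In CPT the levels of Pim1, Gdf2 and Ddc differed from NC by 0.05, 0.10 and -0.08 (adjusted p = 0.945, 0.685 and 0.889). Independent lists would share 0.0140 genes from lower to higher and 0.00113 from higher to lower, and 100 simulations with shared HFD arrays gave 0. Here too 0 simulations had calls in both contrasts, so the 0 gives no chance level. With the HFD arrays split, 0 genes were called in both contrasts by limma in any of 20 splits, and in 18 of them CPT against the remaining HFD arrays had 0 calls. At an unadjusted p under 0.05 in both contrasts, a median of 180 genes of opposite sign were found in these splits, from 156 to 195, and a median of 62.5 of the same sign. The median slope of CPT minus HFD on HFD minus NC over the genes called in these splits, 2 to 48 per split, was -0.02, from -0.22 to 0.07. The remaining HFD arrays minus NC had a median slope of 0.84 on the same axis, so a full return would be weaker than -1. Over the 458 to 718 genes at an unadjusted p under 0.01 the slope of CPT minus HFD was -0.15, from -0.19 to -0.11, and that of the remaining HFD arrays was 0.77. The slope of -0.02 changed sign with single arrays, from -0.21 without NC 1 to 0.11 without HFD 4. The covariance of the fold changes was -0.0182, against -0.00934 in the simulations, a difference of -0.00883. With the HFD arrays split it was -0.0108, from -0.0124 to -0.00899, and -0.00693, from -0.00848 to -0.00372, without CPT mice 1 and 4. Serpina7, with -3.46 in HFD against NC, stood at 2.41 in CPT against HFD (adjusted p = 0.181).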

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

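The tests of adipose tissue, of neutrophils, of single mice, of shared arrays and of regrouped mice without CPT mice 1 and 4 below were chosen after the results they bear on were seen, while those of the intensity trend and of the other regroupings were set before.

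Single mice lay far from the other 4 of their group in 22 of 255 groups of gene values and 8 of 117 groups of list means, by a gap over 0.71 of the group's range. Chance gives about 1 in 20 groups, here 12.8 and 5.85, and 0 of 15 array measures did so, where chance gives 0.75. The rule finds only a single mouse, so 2 mice apart together hide each other, as CPT mice 1 and 4 did on the first component. The 0 therefore does not show that no array stood apart. CPT mouse 1 was the mouse apart in 7 of the 30 cases and NC mouse 1 in 4.

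CPT mouse 1 was high in cholesterol synthesis, with a list mean of 1.08 against -1.25 to -0.91 in the other CPT mice, and levels of Sqle at 7.65 (others 2.48 to 2.70), Nsdhl at 7.84 (4.27 to 4.82), Cyp51 at 7.26 (2.22 to 3.53) and Dhcr7 at 5.76 (4.37 to 4.65). It was also high in Baiap2 at 4.50 (3.64 to 3.80) and low in Gpat4 at 6.53 (7.30 to 7.45). CPT mouse 4 was high in Hsph1 at 7.01 (4.59 to 5.21), Klf10 at 5.13 (3.78 to 4.17) and Irs2 at 4.67 (4.03 to 4.17). CPT mouse 2 was low in Rps12-ps24 at 6.39 (6.70 to 6.78), and CPT mouse 5 high in Il1b at 5.24 (2.78 to 3.48). HFD mouse 1 was high in Acaca at 5.12 (4.50 to 4.66) and low in oxidative phosphorylation at 0.0012 (0.06 to 0.08). HFD mouse 3 was high in Cyp7a1 at 9.69 (8.46 to 8.71) and in bile acid synthesis at 0.59 (0.35 to 0.38), and low in S100a8 at 1.33 (1.65 to 1.77). HFD mouse 2 was high in Hspa1b at 6.63 (4.54 to 5.00) and HFD mouse 5 low in Cxcl13 at 2.28 (3.50 to 3.70).

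NC mouse 1 was low in the unfolded protein response at -0.25 (0.02 to 0.10) and high in Ddc at 5.17 (4.85 to 4.90), in female-biased genes at 0.39 (-0.17 to -0.01) and in cholangiocyte markers at 0.24 (-0.09 to -0.03). NC mouse 2 was high in Susd4 at 5.60 (3.90 to 4.37). NC mouse 3 was low in Fasn at 6.95 (7.68 to 7.94) and in Col1a1 at 3.47 (3.63 to 3.68), and high in exocrine pancreas markers at 0.40 (-0.14 to -0.07). NC mouse 4 was low in Gpat4 at 6.49 (6.86 to 6.99), in Txnip at 7.38 (8.72 to 9.13) and in lipid droplet genes at -0.46 (0.03 to 0.16).

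The first pattern weighed is that CPT mice 1 and 4 stood apart from the other mice, with Cidec high in both. Fabp4 was at 8.13 and 6.94 in these arrays, but NC mouse 3 stood at 7.04. Adipose tissue in the liver piece would bring its own abundant transcripts, but the mean of Adipoq, Plin1, Retn and Lep was at most 1.96 in these arrays, below the highest of the other 13 arrays at 2.04. An intensity trend of the array would fall away when removed by loess. CPT mouse 4 moved only from 0.327 to 0.326 (root mean square, log2) from the other CPT mice. CPT mouse 1 moved from 0.298 to 0.294. Both stayed above the highest of NC and HFD, 0.254. This argues against a smooth trend left in the RMA values as the source in these 2 arrays. CPT mice 2 and 3, at 0.259 and 0.264, also lay above 0.254, but each was compared with a rest of the group that held CPT mice 1 and 4. A different response of these livers to the treatment may be the source and stays open as a hypothesis, as do differences in the handling of these mice or samples, for which the labels give no batch.

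The second pattern is the lower level of acute phase genes in HFD than in NC. RNA of infiltrating neutrophils in the NC mice with the highest acute phase means stays open: 0 of the 2 such arrays had S100a8 and S100a9 below the NC medians, but NC mouse 5 is itself that median, so this rests on NC mouse 4. It stays open as the whole cause in the NC mice too, since 1 of the 2 NC arrays with S100a8 no higher than in HFD had an acute phase mean above every HFD array (NC mouse 2) and the other did not (NC mouse 1). Acute phase means of CPT and HFD mice did not overlap (-0.57 to -0.05 and -1.30 to -0.65). Their neutrophil list means did (-0.47 to -0.25 and -0.52 to -0.40). CPT mice 2 and 4, at -0.456 and -0.473, lay among the HFD mice in neutrophil markers. CPT mice 1, 3 and 5, at -0.357, -0.398 and -0.247, lay above the highest HFD mouse, -0.402. S100a8 and S100a9 were dim in both groups, at most 2.22 and 2.12. As far as such dim markers can show, this argues against neutrophil RNA as the whole cause of acute phase levels in CPT mice 2 and 4 only. It stays open in CPT mice 1, 3 and 5, and the comparison does not cover the NC mice. Differences between single mice stay open: the exact two-sided permutation p was 0.0397, but 0.116 adjusted over the 39 lists, and NC mouse 1, at -1.22, lay among the HFD mice (-1.30 to -0.65). An effect of the diet on these genes may be considered only beside them.

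The third pattern is the opposite sign of fold changes in HFD against NC and in CPT against HFD. Shared HFD arrays would give it, but with these arrays split the median covariance over genes was -0.0108 and the highest of the splits was -0.00899. With all mice 2 of 100 regroupings, the real one included, were as low as the real -0.01076, fewer than the limit set beforehand. The lowest other lay below the real one, at -0.01080. Without CPT mice 1 and 4 the median covariance was -0.00693, from -0.00848 to -0.00372, and 9 of 100 regroupings of the other 13 mice were as low (lowest other -0.0186). Regrouping all mice asks whether the 3 groups are alike. It cannot tell a return from a diet effect without one, so chance is not excluded for a return. A technical offset common to the HFD arrays was not tested, since no slide or scan date was at hand, and a partial return of diet effects in the treated mice may be considered only beside it. A change of diet during the treatment, which the labels leave unclear, stays open as well.

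Other groupings of the same mice were used to ask whether chance can give as many calls. For genes, 1 of 100 splits, the real one, reached each count. The real 87 in HFD against NC stood against at most 9 in the other splits. The 6 in CPT against HFD stood against at most 1, and the 102 in CPT against NC against at most 11. This argues against groups that do not differ at all. It does not show which single calls hold, since the other splits mix the groups and a real difference lowers their counts. The 6 calls of CPT against HFD became 0 without HFD 1, 2, 4 or 5. For the 3 genes that changed in opposite directions the regroupings decide nothing: 1 of 100, the real one, had as many and the highest of the others was 0, but 0 of the other 99 had calls in both contrasts. For counts of lists chance cannot be excluded. At least the 16 lists of HFD against NC were reached by 6 of 100 splits (highest other 19). The 9 lists of CPT against HFD were reached by 7 (13), and the 13 lists of CPT against NC by 13 (16).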

How the results depend on the processing

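Leaving out CPT mice 1 and 4 and the exact permutation of list means were added after seeing the data, and fry was counted as an alternative then. For HFD against NC the 87 genes became 148 with only the 2 groups in the fit (72 shared), 167 with array weights (87 shared), 207 without CPT mice 1 and 4 (87 shared) and 13 with a plain test per gene without moderation (9 shared), and 33 to 148 with 1 array left out. For CPT against HFD the 6 genes became 1 with only the 2 groups, 2 with a variance trend and robust moderation and 0 with the plain test, and 0 to 19 with 1 array left out, where limma gave 2329 genes at an unadjusted p under 0.05 with all arrays. For CPT against NC the 102 genes became 34 with only the 2 groups and 2 with the plain test. The 3 genes that changed in opposite directions became 0 with only the 2 groups, 0 with the plain test, 1 with trend and robust moderation, 1 without CPT mice 1 and 4, a gene other than the 3, and 0 to 4 with 1 array left out. The median slope of -0.02 with the HFD arrays split became -0.15 with genes called at an unadjusted p under 0.01, and lay between -0.21 and 0.11 with 1 array left out. With an estimated correlation list calls fell to 0 for HFD against NC, 0 for CPT against HFD and 1 for CPT against NC. In that order they fell to 3, 0 and 1 by fry and to 0 in each by exact permutation of list means. By permutation 16, 5 and 6 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.0516, 0.155 and 0.124. With 5 mice per group this permutation cannot give a p under 0.00794, and lists at that p gave these smallest adjusted values. For those lists the permutation cannot tell whether the call was lost. The 9 lists of CPT against HFD were 4 to 14 with 1 array left out. The cause of these changes was not tested.

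Mouse number as a block gave 37 genes for HFD against NC, 0 for CPT against HFD and 76 for CPT against NC, and 0 that changed in opposite directions. The numbers do not pair the mice: the deviations of mice with the same number had a mean correlation of -0.0346 (1 of 15 over 0.1), and in 2 of these 15 pairs a mouse matched its own number best in the other group.

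All other alternatives left the counts within 1.5 times: 25 of 36 counts of genes and 27 of 36 counts of lists, and, with 1 array left out, 32 of 45 and 41 of 45. Of 5182 values of named genes 4952 kept their side of the threshold, 147 lost it and 83 gained it, and with 1 array left out 7552 of 7830 kept it. Of 1404 values of single lists 1238 kept their side, 143 lost it and 23 gained it, and with 1 array left out 1649 of 1755. The 143 include those lost by exact permutation, whose smallest p is given above. In these alternatives 0 results past the threshold changed sign. Without scanner values the share of genes near background is not known here, and the number of arrays limits the precision.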

Other observations

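The test of carbohydrate-responsive genes below was chosen after the falls of Khk, Tkfc and Pklr had been seen. Jchain stood at 4.55 ± 1.00 in NC, 2.55 ± 0.23 in HFD and 2.31 ± 0.41 in CPT (SD, n = 5 each), and Cxcl13, the chemokine that draws B cells, at 6.37 ± 1.52, 3.34 ± 0.60 and 4.43 ± 0.62. Ighm, the heavy chain of IgM, differed by -0.95 in HFD and -1.0 in CPT against NC (limma adjusted p = 0.157 and 0.117). The list of B and plasma cell markers did not pass in HFD against NC (mean -0.30, camera adjusted p = 0.0991), with 4 of its 10 members higher, and did so after a further quantile normalization (adjusted p = 0.0276) or without NC 1 (0.0355). Its shift in CPT against NC is given with the other lists above. Hspa1b differed by 1.52 in HFD against NC (limma adjusted p = 0.0532) and Asns by 2.07 (adjusted p = 0.0601), neither past the threshold, and both passed in CPT against NC. The list mean of the abundant hepatocyte markers moved little, from -0.07 to 0.10 in all 15 mice. Such a mean can hide single members that differ in opposite directions. Markers of red blood cells were highest in NC mouse 3, with a list mean of 0.92.

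Khk, Tkfc and Pklr, which handle fructose and the last step of glycolysis, fell in HFD and in CPT against NC, and a lower carbohydrate response of the liver is a candidate explanation to be tested on other genes. The mean of 7 genes known to respond to glucose through ChREBP or closely linked to sugar use, Txnip, Arrdc4, G6pc, Gpd1, Slc2a2, Tm6sf2 and Mlxipl, was lower in HFD than in NC by -0.61, with an exact two-sided permutation p of 0.00794, the smallest that the splits of 10 mice can give. All 7 genes were lower, all 5 HFD mice lay below the NC mean, and 0 of the genes passed by limma over all genes, with Txnip at -0.92 (adjusted p = 0.251) and Tm6sf2 at -0.80 (adjusted p = 0.116), where 5 had an unadjusted p under 0.05. Since 3 of the 7 are on other lists, the remaining 4 were taken alone, with a mean of -0.58 and an exact permutation p of 0.00794. The mean differed by -0.66 in CPT against NC (exact permutation p = 0.00794) and by -0.06 in CPT against HFD (exact permutation p = 0.746). The values go with the explanation, which remains a hypothesis. The diet that replaced part of the standard diet with fat and the insulin level of these fasted mice could each be its source. Per the labels the fast was 12 h in all groups, and insulin was not measured here.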
